A study of Mus musculus with 18 samples.

How the data were processed

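The RNA of 3 populations of blood-forming cells, sorted from the bone marrow of adult male C57BL/6 mice, was sequenced after treatment with tamoxifen or with the corn oil vehicle. The series' design text calls the populations LT-HSCs, ST-HSCs and MPPs. Here LT and ST stand for the long-term and short-term haematopoietic stem cells and MPP for the multipotent progenitors, which are the field's usual readings of these names. MPPs came from mice treated for 1 week, and LT and ST cells from mice treated for 2 weeks. The 6 groups held 3 libraries each, 18 in all, and the series' design text calls the 3 biological replicates. Per the labels' protocols, RNA was extracted with the Picopure kit, cDNA was made and amplified with the Ovation RNA-Seq System V2, and adaptors were ligated after sonication as in the TruSeq DNA kit. The antibodies and gates of the sort, and whether 1 library came from 1 mouse, are not given in the sources used here.

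The authors deposited 1 table of normalised values for 14419 genes. Per the submitters' processing notes, the tools were Picard, cutadapt, RSEM 1.17 and limma, and the genome build was NCBIM37. The scaling method, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values were treated as a normalised signal on a linear scale. In each library every value equals a whole number of reads, plus 0.5 read, times 1 constant. With a tolerance of 0.001 read, 100% of the values came out whole, and the largest deviation was 2.7e-08. The values therefore have the form of CPM (read counts scaled to a common library total), and they are called normalised CPM here. RSEM itself gives fractional expected counts, and how whole numbers arose is not given in the sources used here, so the recovered reads can be rounded estimates. Every gene reached 1 in at least 6 libraries, so the authors had already left out low genes. Of the genes, 120 had no symbol in the table and 116 shared a symbol with another. The gene identifier was used to tell these apart.

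The recovered reads in the listed genes numbered from 2728800 (ST oil library A) to 5279821 (MPP tamoxifen library 1) per library. Genes near 1 normalised CPM therefore rest on a few reads per library. The cDNA was amplified and no molecular identifiers were used here, so counting intervals (95%, exact) and floors (3 reads over a group of 3 libraries) cover counting error only, and both rest on the recovered reads being counts.

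Genes were compared with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, on log2(value + 1). All 18 libraries entered 1 fit with 1 mean per group, which left 12 residual degrees of freedom. Moderated variances were fitted with a trend on mean expression and robustly, and p-values were adjusted by the Benjamini-Hochberg method over 14419 genes at a threshold of 0.05. A planned filter (a value of 1 in at least 3 libraries) removed no gene. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The comparisons were tamoxifen against oil in each population, the pairwise differences of these 3 effects, and ST against LT cells in oil. MPP libraries differ from the others in both population and duration, so these cannot be separated in any comparison of MPPs with LT or ST cells. The sample titles number MPP and LT libraries together and ST libraries anew. They do not say whether ST libraries were prepared or sequenced apart from the rest.

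A set of 29 gene lists was tested with limma's camera (preset correlation between genes of 0.01), with adjustment over the 87 tests of the lists in the 3 tamoxifen comparisons. Camera with an estimated correlation and fry were run beside it. The lists were estrogen receptor targets, p53 targets, pro-apoptotic and anti-apoptotic members of the BCL2 family, death receptors and caspases, ribosome biogenesis with MYC targets, DNA replication, mitosis, and CDK inhibitors with quiescence genes. Further lists held long-term HSC genes, multipotent progenitor genes, granulocyte-monocyte, megakaryocyte-erythroid and lymphoid-primed genes, and JAK-STAT signalling genes. The unfolded protein response, the interferon response, cholesterol biosynthesis, oxidative phosphorylation, glycolysis with hypoxia, the antioxidant response, immediate early genes and mitochondrially encoded genes had a list each. Markers of mature neutrophils, erythroblasts, B cells, T and NK cells, macrophages and monocytes, and stroma and endothelium stood for other cells that a sort could hold. The lists were written from general knowledge of the pathways and cell types.

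Genes are named by a rule. It takes Esr1, Esr2 and Gper1, and in each comparison the 8 rising and the 8 falling genes with the largest change among those past the threshold. These had a mean above the median gene, groups that did not overlap, and no provisional symbol. From each list it takes the 3 members with the smallest p among those past the threshold, or 1 member where none passed. For differences of response it takes up to 5 genes per direction. Esr2 and Gper1 were not analysed here. Genes outside the rule are marked as chosen after their values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, logs with nothing added, removal of length and GC trends, thinning to 1 depth, and leaving LT tamoxifen library A out of the shared fit. Depth in the thinning means the effective library size, the total by which the normalised CPM were scaled, not the number of reads in listed genes.

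The procedure was tested on simulated reads for 14419 genes, of which 200 were changed. Means and depths were taken from the data. Each gene had 1 spread for all groups, so the wider spread of LT tamoxifen library A was not reproduced. Low genes were left out of the draw of changed genes, so recovery was not measured for genes as low as Greb1. In the MPP comparison the procedure recovered 73% of the genes changed 2-fold and 100% of those changed 4-fold, in the LT comparison 66% and 96%, and in the ST comparison 69% and 95%. It also called 12, 7 and 8 unchanged genes, respectively. Transcript length and GC content came from the GENCODE vM21 annotation of GRCm38, matched by gene identifier for 13693 genes (95%). That is another build than the authors' and no coordinates are given. Within groups, libraries correlated at 0.947 to 0.98 (Pearson, across genes), and no 2 libraries of a group agreed within counting noise. Reads shared by the globin paralogs, by mt-Rnr2 and Lars2, and by antisense pairs cannot be assigned with certainty, and values of such genes are uncertain. Leave-one-out fits were run for every library of the groups compared. All 18 columns of the table were used, and no other file of the series was used here.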

Results

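The transcriptomes of MPPs, LT cells and ST cells were measured by RNA-seq in male mice given tamoxifen, a selective estrogen receptor modulator, or corn oil. Each of the 6 groups held 3 libraries. The reads in listed genes numbered 3664203 to 3928747 in MPP oil, 3558988 to 5279821 in MPP tamoxifen, 3361891 to 4560482 in LT oil, and 3203195 to 3857229 in LT tamoxifen. They numbered 2728800 to 3267591 in ST oil and 3611749 to 3982982 in ST tamoxifen. Values below are normalised CPM, given as the mean ± SD of 3 libraries. The first 2 principal components held 28.3% and 20.2% of the variance and parted the 3 populations. LT tamoxifen library A lay apart from the other LT libraries on the fourth component. The mitochondrial ribosomal RNAs took 25.4% of its reads, against 17.7% and 18.6% in the other LT tamoxifen libraries and 18.1% to 18.7% in LT oil. Outside LT cells the share reached 24.3%, in ST tamoxifen library A.

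The gene of estrogen receptor alpha, Esr1 (ENSMUSG00000019768), was measured in all 3 populations, at 78.5 ± 10.5 in MPP oil, 40.4 ± 3 in LT oil and 36.7 ± 8.96 in ST oil. With tamoxifen it fell to 17.7 ± 8.96 in ST cells (log2 fold change -1.13, limma adjusted p = 0.0149, 0.0029 to 0.0743 over the alternatives). This call was lost without ST oil library C (0.0566), without ST tamoxifen library C (0.0743) or with the replicate number as a block (0.0554). In LT cells Esr1 stood at 22.9 ± 5 with tamoxifen (log2 fold change -0.81, adjusted p = 0.186), and in MPPs at 58.7 ± 7.73 (-0.41, 0.936). Esr1 did not differ detectably between ST and LT cells in oil (adjusted p = 0.723).

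To ask what 1 week of tamoxifen changed in MPPs, the 2 MPP groups were compared. Greb1, a gene known to be induced by estrogen receptor alpha, rose from 0.504 ± 0.32 to 5.29 ± 2.05. Ermap, a protein of the erythroid membrane, rose from 4.81 ± 1.27 to 26.1 ± 15.9, and Ank1, the ankyrin of the red cell membrane skeleton, from 1.58 ± 0.512 to 10.3 ± 7.54. Asns, the asparagine synthetase, rose from 6.52 ± 0.614 to 15.4 ± 1.39, and Aldh1a1, a retinaldehyde dehydrogenase, from 0.681 ± 0.464 to 5.51 ± 3.09. Pdgfrb (ENSMUSG00000024620), the beta receptor for platelet-derived growth factor, fell from 55.2 ± 8.84 to 22 ± 9.52. The organic cation transporter gene Slc22a3 fell from 89.7 ± 6.06 to 51.1 ± 7.88, and 2900026A02Rik from 101 ± 20 to 56.6 ± 2.23.

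These were all the genes that passed in MPPs: 8 of 14419, of which 5 were higher and 3 lower, with 819 genes at an unadjusted p under 0.05. Ank1, Aldh1a1 and 2900026A02Rik fall outside the naming rule and were chosen after their values were seen. Limma's adjusted p ran from 0.00592 (Aldh1a1) to 0.0491 (Ermap, Pdgfrb and 2900026A02Rik). It was 0.0305 for Greb1 (0.00118 to 0.162 over the alternatives) and 0.0491 for Pdgfrb (0.00104 to 0.497). Greb1 rested on 4 reads in oil and 64 with tamoxifen, a ratio of 13.7 (exact 95% counting interval 5.09 to 51.7). The groups did not overlap in 2147 genes (14.9%), where chance gives 10%. With edgeR 2 genes were higher and 3 lower, and with DESeq2 15 and 13. Library weights gave 67 genes, only the groups compared 19, the shared fit without LT tamoxifen library A 22, the removal of length and GC trends 5, and a fit without trend and robust settings 2. Leaving out a library gave 0 genes without MPP oil library 2 (560 unadjusted) or MPP tamoxifen library 2 (725 unadjusted), 1 without oil library 1, 3 without tamoxifen library 3, and 40 without oil library 3.

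Of the 29 lists, 15 shifted in MPPs by camera, and each of these calls was lost with an estimated correlation. Few of their members passed singly. The unfolded protein response shifted upward (median log2 fold change 0.29, 20 of 23 members above 0). Its member Asns rose, and 4 members passed when adjusted over the list alone. The adjusted p was 2.37e-09, and 0.0606 with an estimated correlation. Oxidative phosphorylation had 32 of 35 members above 0 and none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 6.33e-08, adjusted p = 0.271 with an estimated correlation). Its member with the smallest p, Ndufa4, stood at 77.7 ± 19.4 in oil and 116 ± 16.4 with tamoxifen. Megakaryocyte-erythroid genes shifted upward (1.83e-05, adjusted p = 0.254 with an estimated correlation), with 1 of 21 members past the threshold and 5 adjusted over the list alone. One of the latter, the carbonic anhydrase gene Car1, stood at 9.29 in oil and 53.3 with tamoxifen (adjusted p = 0.064 over all genes). It was chosen after its values were seen.

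Erythroblast markers shifted upward beside these genes, with all 15 members above 0 and a median log2 fold change of 0.85. None of the 15 passed over all genes or adjusted over the list alone (camera adjusted p = 9.65e-08, adjusted p = 0.261 with an estimated correlation). The list's call was lost without MPP tamoxifen library 2 (0.254). Haemoglobin Hbb-b1, whose reads cannot be parted with certainty from those of its paralogs, stood at 153 in that library and at 21.8 and 2.42 in the other MPP tamoxifen libraries (adjusted p = 0.959). In the same library Ermap stood at 43.2, Ank1 at 18.9 and Car1 at 81.8, and without it Ermap had an adjusted p of 0.058. Spnb1, the erythroid beta spectrin, had the smallest p of the list and stood at 2.61 ± 1.64 in oil and 11.2 ± 12.3 with tamoxifen.

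Cell division and biosynthesis lists also shifted upward in MPPs, with 0 members past the threshold over all genes or adjusted over the list alone in the first 3. Ribosome biogenesis had 29 of 30 members above 0 (0.000268, adjusted p = 0.254 with an estimated correlation), mitosis 29 of 30 (8.97e-05, adjusted p = 0.538 with an estimated correlation) and DNA replication 23 of 30 (0.000741, adjusted p = 0.374 with an estimated correlation). Glycolysis with hypoxia (0.0031, adjusted p = 0.452 with an estimated correlation) had 2 members, Vegfa and Pgam1, past the threshold when adjusted over the list alone. The antioxidant response (0.00202, 0.298 estimated), interferon response (0.0031, 0.5 estimated), granulocyte-monocyte genes (0.00269, 0.389 estimated), immediate early genes (0.00145, 0.468 estimated) and macrophage markers (0.0144, 0.271 estimated) shifted upward with 0 members past the threshold in either adjustment. Downward shifts were seen for lymphoid-primed genes, with 4 of 20 members above 0 and none past the threshold in either adjustment (0.0028, adjusted p = 0.256 with an estimated correlation), and for multipotent progenitor genes (0.0358, adjusted p = 0.639 with an estimated correlation). In the last list Ccr2 was higher and Cd33 lower when adjusted over the list alone. Of these lists mitosis, multipotent progenitor, granulocyte-monocyte, interferon, antioxidant, immediate early and macrophage genes each lost the call without at least 1 MPP library, and a stricter filter on low values ended the multipotent progenitor (0.0549), interferon (0.0515) and immediate early (0.0599) calls and quantile normalisation the multipotent progenitor call (0.0623). By fry only the unfolded protein response passed of the 15 (0.0151).

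After 2 weeks of tamoxifen in LT cells, Mpo, the myeloperoxidase of granulocyte precursors, fell from 93 ± 9.33 to 19.8 ± 5.11, and Dntt, the terminal deoxynucleotidyl transferase of early lymphoid cells, from 19.1 ± 4.19 to 2.93 ± 3.28. Satb1, a chromatin organiser that promotes lymphoid fate, fell from 59.5 ± 18 to 24 ± 7.86. In oil, Mpo, Dntt and Satb1 stood higher in MPPs (811, 436 and 453) and in ST cells (1100, 36.9 and 91.1) than in LT cells. Gstm1, which also fell in LT cells, stood lower in MPPs (113) and ST cells (69.6) than in LT cells (122). Whether the mix of sorted LT cells changed was not tested. Pdgfrb fell from 19.7 ± 1.61 to 4.23 ± 2.09. The receptor gene Kit fell from 1090 ± 61.2 to 741 ± 52.6, while Ldha, a lactate dehydrogenase, rose from 362 ± 40.2 to 545 ± 14.2 and the interferon-induced Oas2 from 24.7 ± 7.72 to 58.4 ± 17.6.

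In all, 60 genes passed in LT cells, 20 higher and 40 lower, and 35 of them changed over 2-fold. At an unadjusted p under 0.05 there were 1952. The split was 30 higher and 68 lower after quantile normalisation, 26 and 32 with edgeR, and 178 and 122 with DESeq2. The groups did not overlap in 2653 genes (18.4%, against 10% by chance). The smallest adjusted p values were those of Dhrs3, a retinal reductase chosen after its values were seen, which fell from 15.5 ± 6.58 to 2.11 ± 0.438 (limma adjusted p = 0.000131), and Pdgfrb (0.00019, 2.34e-07 to 0.0674 over the alternatives). Atp8b4, a phospholipid flippase gene, fell from 23.9 ± 4.37 to 5.74 ± 0.153 (0.000608), and Mdga1 from 84.8 ± 12.1 to 43.8 ± 3.22 (0.000609). Dpp4, Mc5r and Ypel3 also fell. Slfn9, Ankrd49, Timm8a1, Cops2, Coro2a, Eif2s1 and Ncaph, a subunit of condensin, rose, with adjusted p from 0.0153 to 0.0437. Greb1 had 0 reads in LT oil and 12 with tamoxifen, and did not pass (limma adjusted p = 0.179). The tamoxifen value was 4.75-fold higher than a floor of 3 reads over the oil group, with the counting error of the 12 reads not included.

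The LT calls moved with single libraries. Their number was 20, 33 and 9 without LT oil library A, B or C, 330 without LT tamoxifen library B, 3 when the LT groups were fitted alone, 235 with library weights, and 22 without trend and robust settings. Of 21 named genes past the threshold, 6, 7 and 4 kept the call without oil library A, B or C, and 9, 21 and 12 without tamoxifen library A, B or C.

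Among the lists, 12 shifted in LT cells by camera, and each of these calls was again lost with an estimated correlation. Lymphoid-primed genes shifted downward (median log2 fold change -0.69, camera adjusted p = 6.01e-07, adjusted p = 0.0606 with an estimated correlation). Dntt and Satb1 fell and 18 of 20 did not pass, while 8 fell when adjusted over the list alone. Multipotent progenitor genes shifted downward with 0 of 17 members above 0 (5.38e-11, adjusted p = 0.163 with an estimated correlation). Dntt and Satb1 fell here too, and 8 members fell when adjusted over the list alone, among them Cd34, Flt3 and Cd48. Granulocyte-monocyte genes shifted downward (0.00792, adjusted p = 0.452 with an estimated correlation), with Mpo and Gfi1 past the threshold and 3 members adjusted over the list alone. Gfi1, a transcription repressor that restrains stem cell proliferation and is needed for granulocytes, fell from 12.1 ± 2.93 to 5.19 ± 2.97. It was also the member of the CDK inhibitor and quiescence list that fell, and 17 of the 20 members of that list lay below 0 (0.00269, adjusted p = 0.235 with an estimated correlation). Adjusted over the list alone, Gfi1, Ccng2 and Foxo3 fell and Rbl1 rose. B cell markers shifted downward with 0 of 11 members past the threshold in either adjustment (0.00878, adjusted p = 0.374 with an estimated correlation), Cd74 standing at 77.3 ± 15.1 in oil and 50.4 ± 18.5 with tamoxifen.

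Lists of dividing cells shifted upward in LT cells although no member passed over all genes. Mitosis had 28 of 30 members above 0 and a median log2 fold change of 0.51 (2.39e-13, adjusted p = 0.271 with an estimated correlation), and 16 members rose when adjusted over the list alone. The mitotic spindle gene Hmmr had its smallest p and stood at 57.6 ± 5.92 in oil and 102 ± 30.9 with tamoxifen (adjusted p = 0.0731 over all genes). DNA replication (7.55e-09, adjusted p = 0.182 with an estimated correlation) had 9 members that rose when adjusted over the list alone, led by the primase gene Prim1 at 41.9 ± 4.21 and 64.7 ± 8.69. Ribosome biogenesis (8.53e-09, adjusted p = 0.0606 with an estimated correlation) had 12, led by Nop58 at 197 ± 4.5 and 283 ± 51.3. The interferon response shifted upward (median 0.44, 3.41e-10, adjusted p = 0.224 with an estimated correlation). Oas2 rose, and adjusted over the list alone 11 members rose and 1, Gbp2, fell. Megakaryocyte-erythroid genes (0.0368, adjusted p = 0.507 with an estimated correlation) had Vwf, von Willebrand factor, past the threshold only when adjusted over the list alone, at 107 ± 16 and 168 ± 21.2.

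Mitochondrially encoded genes shifted upward with all 13 above 0 (median 0.67, 5.26e-07, adjusted p = 0.374 with an estimated correlation), and 1, mt-Co3, rose when adjusted over the list alone. This call was lost without LT tamoxifen library A (0.217), the library with the high mitochondrial ribosomal share. Oxidative phosphorylation genes of the nucleus (0.0373, adjusted p = 0.684 with an estimated correlation) had 0 of 35 members past the threshold in either adjustment, and their median of 0.09 lay at percentile 94.21 of 10000 random lists matched on expression. Their call was lost without LT oil library C (0.264), tamoxifen library B (0.359) or tamoxifen library C (0.987, where the direction reversed). The megakaryocyte-erythroid call was lost without oil libraries A or C or tamoxifen libraries B or C (0.0846 to 0.196), the granulocyte-monocyte call without tamoxifen library A (0.0949) and the B cell call without oil library B (0.233). With a stricter filter on low values the CDK inhibitor (0.0981), megakaryocyte-erythroid (0.216), oxidative phosphorylation (0.108) and B cell (0.0599) calls were lost, and after quantile normalisation the megakaryocyte-erythroid (0.105) and oxidative phosphorylation (0.103) calls. Fry did not call mitosis (0.0939), granulocyte-monocyte (0.213), megakaryocyte-erythroid (0.411), oxidative phosphorylation (0.635), mitochondrially encoded (0.228) or B cell genes (0.213).

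In ST cells, 2 weeks of tamoxifen were followed by the broadest change. Cad, which starts pyrimidine synthesis, rose from 49.9 ± 7.81 to 107 ± 23.7, cyclin A2 (Ccna2) from 119 ± 15.3 to 230 ± 11.4, and the chaperone gene Hsp90b1 from 680 ± 110 to 1220 ± 59.7. Greb1 had 0 reads in oil and 40 with tamoxifen, 11.3-fold higher than a floor of 3 reads over the oil group. The counting error of the 40 reads is not included in this value. The nuclear RNA Neat1 fell from 333 ± 51.8 to 162 ± 44.7, and Malat1, another nuclear RNA, chosen after its values were seen, from 7890 ± 772 to 3960 ± 492. Pdgfrb fell from 37 ± 4.84 to 9.84 ± 1.07.

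In ST cells 1386 genes passed, 867 higher and 519 lower (62.6% higher), and 360 of them changed over 2-fold. At an unadjusted p under 0.05 there were 3614. After quantile normalisation 606 were higher and 554 lower (52.2% higher). The groups did not overlap in 3892 genes (27%, against 10% by chance). Among genes with a mean above that of the median gene, groups that did not overlap and no provisional symbol, the largest rises were those of Ermap (17.4 ± 2.04 to 64 ± 14.5), Ces2g, a carboxylesterase (15.4 ± 4.52 to 52.9 ± 15), and Myh10, a non-muscle myosin (12.8 ± 0.443 to 42.6 ± 10.1). Atp1b2, Spire1, Tgm2, Als2cl and Fads2, a fatty acid desaturase (17.3 ± 3.07 to 44.1 ± 2.5, limma adjusted p = 8.37e-05), followed. Among the same genes the largest falls were those of the syntaxin gene Stx3 (40.4 ± 3.89 to 15.6 ± 4.55), Esr1, Clec2d, Clcf1, Ctla2a, Vasn, Rnf150 and Neat1. Antisense transcripts had a median log2 fold change of -0.56 in ST cells (1 higher and 45 lower), lincRNAs -0.47 (0 and 11), and processed transcripts -0.44 (1 and 18). Protein-coding genes had a median of 0.05 (856 higher and 319 lower). Antisense counts are uncertain without a known strand setting.

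Leaving out a library gave 654 ST calls without oil library A, 904 without oil library B, 855 without tamoxifen library B and 669 without tamoxifen library C, while 2121 passed with LT tamoxifen library A left out of the shared fit. After quantile normalisation Fkbp4 (0.282), Pgk1 (0.0818), Calr (0.057), Emb (0.0603), Jak1 (0.272) and Sdha (0.103) lost the call. Of 65 named genes past the threshold, 47, 53 and 58 kept the call without oil library A, B or C, and 54, 51 and 51 without tamoxifen library A, B or C.

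Ribosome biogenesis with MYC targets was the list whose call held with an estimated correlation (camera adjusted p = 2.58e-13, adjusted p = 0.0394 with an estimated correlation). All 30 members lay above 0, 16 rose, and 18 rose when adjusted over the list alone. Beside Cad, the nucleolar helicase gene Ddx21 rose from 110 ± 8.4 to 209 ± 23.3 and the nucleolar gene Nolc1 from 67 ± 19.4 to 137 ± 7.71. Mitosis (1.67e-12, adjusted p = 0.271 with an estimated correlation) had 11 of 30 members that rose, and 24 adjusted over the list alone. Among them were Plk1, a mitotic kinase (17.1 ± 3.65 to 37.4 ± 5.37), and cyclin B1 (Ccnb1, 61.4 ± 15.9 to 117 ± 10.5). DNA replication (2.46e-06, adjusted p = 0.256 with an estimated correlation) had 10 of 30, and 11 adjusted over the list alone, with the helicase subunits Mcm6 (186 ± 17.3 to 290 ± 10.7) and Mcm2 (105 ± 5.6 to 158 ± 8.48) and the DNA methylation cofactor Uhrf1 (90.7 ± 8.29 to 155 ± 17.3). The unfolded protein response (1.24e-06, adjusted p = 0.134 with an estimated correlation) had 8 of 23 that rose. Adjusted over the list alone 11 rose and 1 fell. Asns rose from 9.4 ± 1.13 to 21.9 ± 1.21 and the chaperone gene Hyou1 from 80.1 ± 11.8 to 130 ± 11.1.

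Glycolysis with hypoxia (0.00121, adjusted p = 0.393 with an estimated correlation) had 7 of 24 members that rose, and 11 adjusted over the list alone, led by Eno1 (165 ± 18.2 to 297 ± 17.2), Ldha (364 ± 33.6 to 586 ± 57.7) and Pgk1 (137 ± 13.9 to 193 ± 10.5). The antioxidant response (0.0031, adjusted p = 0.331 with an estimated correlation) had 3 of 24 in both adjustments, G6pdx (59.1 ± 7.33 to 104 ± 16.8), Gclm and Gsr. Its median, 0.21, lay at percentile 88.89 of 10000 random lists matched on expression. Interferon response genes (9.7e-08, adjusted p = 0.261 with an estimated correlation) had 8 of 36, and 17 adjusted over the list alone, among them Gbp3 (25.3 ± 0.589 to 52.5 ± 5.48), Igtp and Oas3. Megakaryocyte-erythroid genes (0.000193, adjusted p = 0.271 with an estimated correlation) had 6 of 21, and 9 adjusted over the list alone. Beside Ermap, Cpox, an enzyme of haem synthesis, rose from 25.8 ± 6.57 to 63.4 ± 4.9 and the blood group gene Rhd from 1.13 ± 1.21 to 4.01 ± 0.922. Of the 15 erythroblast markers, Rhag (5.75 ± 2.77 to 21.9 ± 5.5) and Spna1, the erythroid alpha spectrin (4.24 ± 2.48 to 14.5 ± 3.74), rose in both adjustments, and the list did not pass (adjusted p = 0.287). Granulocyte-monocyte genes (0.0031, adjusted p = 0.391 with an estimated correlation) had 1 of 20 that rose, the chaperone gene Calr, and 4 adjusted over the list alone. Macrophage markers (0.0266, adjusted p = 0.298 with an estimated correlation) had 1 of 16, Vcam1 (15.3 ± 3.89 to 35.7 ± 1.78), and 2 adjusted over the list alone. The macrophage call was lost without ST oil library B (0.117) or tamoxifen library A (0.0782), and a stricter filter on low values ended the macrophage (0.365), granulocyte-monocyte (0.182) and antioxidant (0.0738) calls. Fry did not call glycolysis with hypoxia (0.063), granulocyte-monocyte genes (0.114) or multipotent progenitor genes (0.219).

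Estrogen receptor targets shifted upward in ST cells (0.0251, adjusted p = 0.272 with an estimated correlation), and this call was lost without oil library A (0.122), without tamoxifen library B (0.0648) or with a stricter filter on low values (0.275). Beside Greb1, cyclin D1 (Ccnd1) rose from 20.3 ± 0.923 to 37.5 ± 1.39 and the immunophilin gene Fkbp4 from 199 ± 35.2 to 293 ± 51.5, and 11 of 14 did not pass. Adjusted over the list alone, 6 rose and 1 fell. The list did not pass in MPPs (0.115, though 0.0384 without MPP tamoxifen library 2) or LT cells (0.42), where Greb1 in MPPs was its 1 member past the threshold and, adjusted over the list alone, Nrip1 fell in LT cells. Multipotent progenitor genes shifted downward in ST cells (0.00652, adjusted p = 0.5 with an estimated correlation), and lost the call without oil library C (0.0624). Ctla2a (254 ± 55.2 to 120 ± 30.9), Ramp1 (88.8 ± 7.42 to 55.9 ± 9.11) and Satb1 (91.1 ± 29.3 to 49.5 ± 10.1) fell and Emb (139 ± 23.5 to 225 ± 52.9) rose. Adjusted over the list alone 6 fell and 1 rose. Satb1 was also the 1 of 20 lymphoid-primed genes that fell, with 0 adjusted over the list alone, and that list did not pass (0.544).

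**Figure D1:**
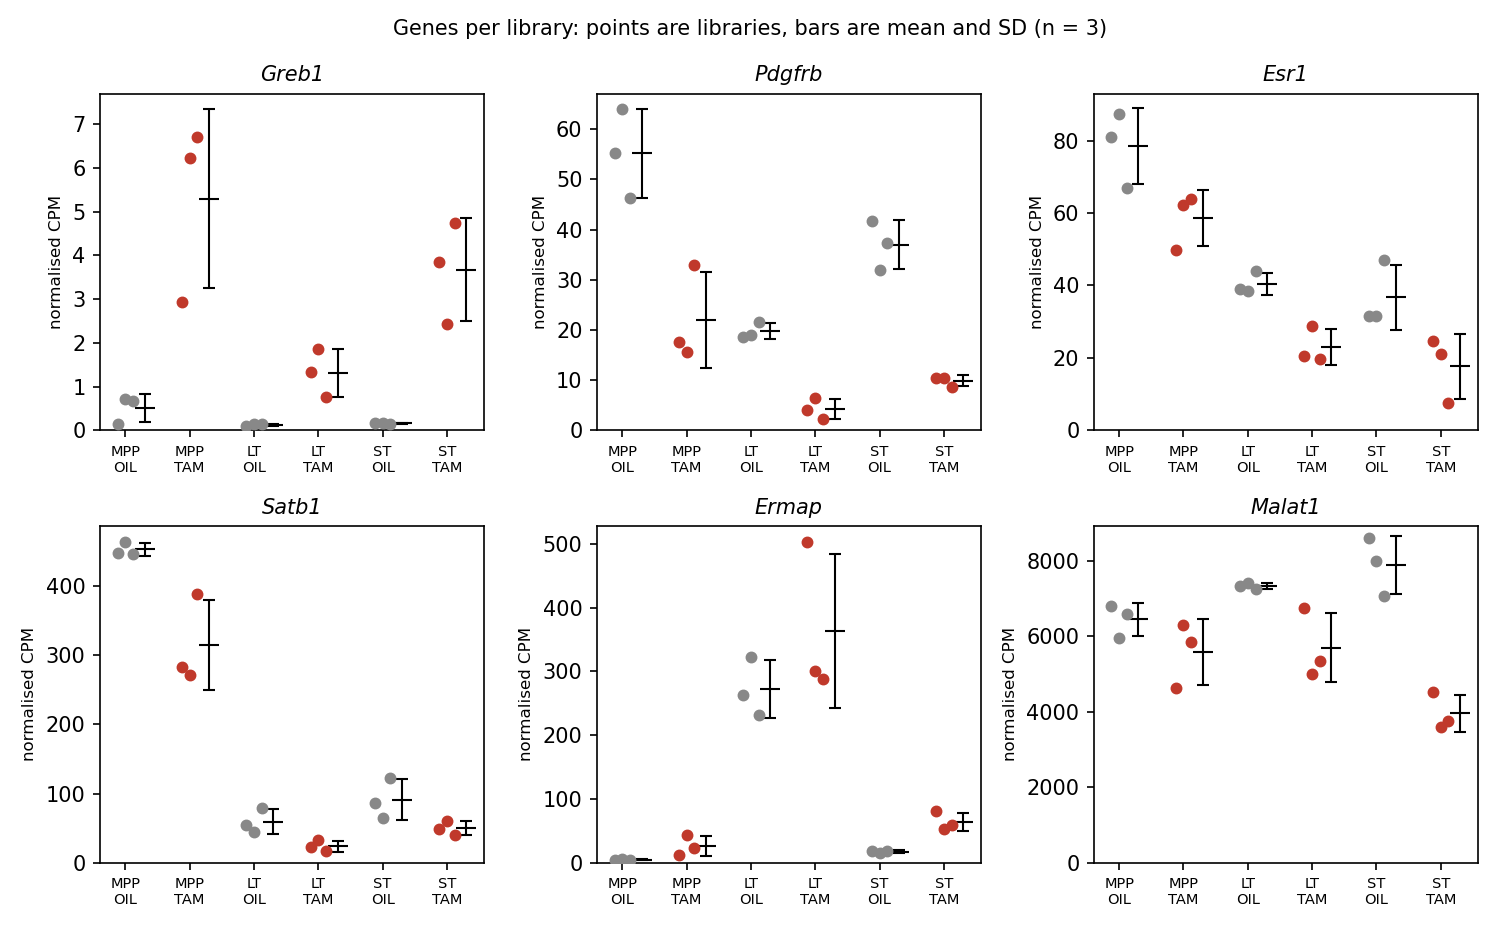
Normalised CPM (vertical axes, from 0) of Greb1, Pdgfrb, Esr1, Satb1, Ermap and Malat1 in the 18 libraries, with 1 point per library and the mean ± SD of each group (n = 3) in oil and tamoxifen. Pdgfrb was lower with tamoxifen in all 3 populations, from 55.2 to 22 in MPPs, 19.7 to 4.23 in LT cells and 37 to 9.84 in ST cells.

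Lists of cell survival genes did not pass camera in any of the 3 populations. No p53 target of 24 passed in any of them in either adjustment (camera adjusted p = 0.484 in MPPs, 0.63 in LT and 0.939 in ST cells). Of the 11 pro-apoptotic BCL2 members 0 passed over all genes, and the list did not pass (0.498, 0.989 and 0.989). In LT cells Bok rose and Bnip3 fell when adjusted over the list alone. Of the 4 anti-apoptotic members 0 passed over all genes, and the list did not pass (0.915, 0.338 and 0.284), though fry called it in ST cells (0.0198, 0.0198 to 0.693 over the alternatives). Bcl2 rose in ST cells when adjusted over the list alone, at 98.7 ± 14.3 in oil and 144 ± 20.1 with tamoxifen. Of 22 death receptor and caspase genes, none passed in MPPs or LT cells in either adjustment (0.989 and 0.989). In ST cells the list did not pass (0.587), while among its members Tnfrsf1b rose and Cflar, a caspase-8 inhibitor (159 ± 8.06 to 118 ± 7.03), fell in both adjustments.

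Long-term HSC genes did not pass as a list in MPPs (0.933), LT cells (0.148) or ST cells (0.177), but passed in MPPs without MPP tamoxifen library 3 (0.0192) and in LT cells after quantile normalisation (0.016, downward) or with a stricter filter (0.0211). In MPPs Kit was lower when adjusted over the list alone. Kit fell in LT cells, where 3 members fell and 1, Vwf, rose when adjusted over the list alone. In ST cells 4 of 31 rose and 1 fell in both adjustments, among them Mecom, a transcription factor of stem cells (93 ± 16.1 to 155 ± 10.8), Tek (22.4 ± 5.12 to 39.5 ± 5.39) and Ctnnal1 (13.8 ± 1.11 to 26.3 ± 5.9). JAK-STAT signalling genes did not pass (0.989, 0.419 and 0.156), but did in ST cells without ST oil library C (0.0374, 0.0374 to 0.684 over the alternatives). Socs2 (8.26 ± 0.992 to 21 ± 3.15) and Jak1 rose in ST cells in both adjustments, and in LT cells Socs2 and Pim2 rose and Bcl6 and Jak3 fell when adjusted over the list alone. Cholesterol biosynthesis did not pass (0.805, 0.582 and 0.0693), but did in ST cells after quantile normalisation (0.0356), without ST oil library C (0.0112) or without ST tamoxifen library A (0.0362). Nsdhl and Sqle were among the members that rose there, and 4 members rose when adjusted over the list alone. Oxidative phosphorylation did not pass in ST cells (0.178), where Atp5b (1110 ± 123 to 1830 ± 125), Sdha and Ndufs1 rose in both adjustments, but it did with length and GC trends removed (0.0236, 0.0236 to 0.831 over the alternatives).

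Neither the CDK inhibitor list (0.659 in MPPs, 0.939 in ST cells, where Ccng2 fell from 54.2 ± 3.98 to 32.4 ± 9.62 in both adjustments) nor immediate early genes (0.246 in LT, 0.758 in ST cells) passed, though the latter did in LT cells without LT oil library A (0.0231) or LT tamoxifen library C (0.0462). The unfolded protein response (0.262), glycolysis (0.834) and the antioxidant response (0.226, where Gstm1 fell from 122 ± 6.37 to 70.6 ± 9.13 in both adjustments) did not pass in LT cells, though the last did without LT tamoxifen library A (0.0056). Mitochondrially encoded genes did not pass in MPPs (0.419) or ST cells (0.503), but did in MPPs without MPP tamoxifen library 1 (0.0212) and in ST cells with length and GC trends removed (0.0238). Markers of neutrophils (0.0597, 0.103 and 0.419 in MPPs, LT and ST cells), T and NK cells (0.913, 0.939 and 0.838) and stroma and endothelium (0.728, 0.212 and 0.989) did not pass, though the last passed with a stricter filter in MPPs (0.0105) and LT cells (0.0141), and by fry in LT cells (0.0457). Neutrophil markers passed in MPPs without MPP oil library 3 (2.57e-06) or MPP tamoxifen library 3 (1.12e-05), and ran up to 0.989 over the alternatives. In LT cells they passed with only the groups compared (0.0169), with length and GC trends removed (0.045) or without LT oil library C (0.00717), and ran up to 0.746. In the stroma and endothelium list Pdgfrb fell in each population while the other 8 measured members did not pass, though Col1a2 rose in MPPs when adjusted over the list alone. B cell markers did not pass in MPPs (0.544) or ST cells (0.807), where Ighm stood at 96.1 ± 27.3 in oil and 305 ± 101 with tamoxifen in groups that did not overlap (log2 fold change 1.64, adjusted p = 0.0857). Nor did erythroblast markers in LT cells (0.183, though 0.0444 with only the groups compared) or macrophage markers in LT cells (0.758).

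**Figure D2:**
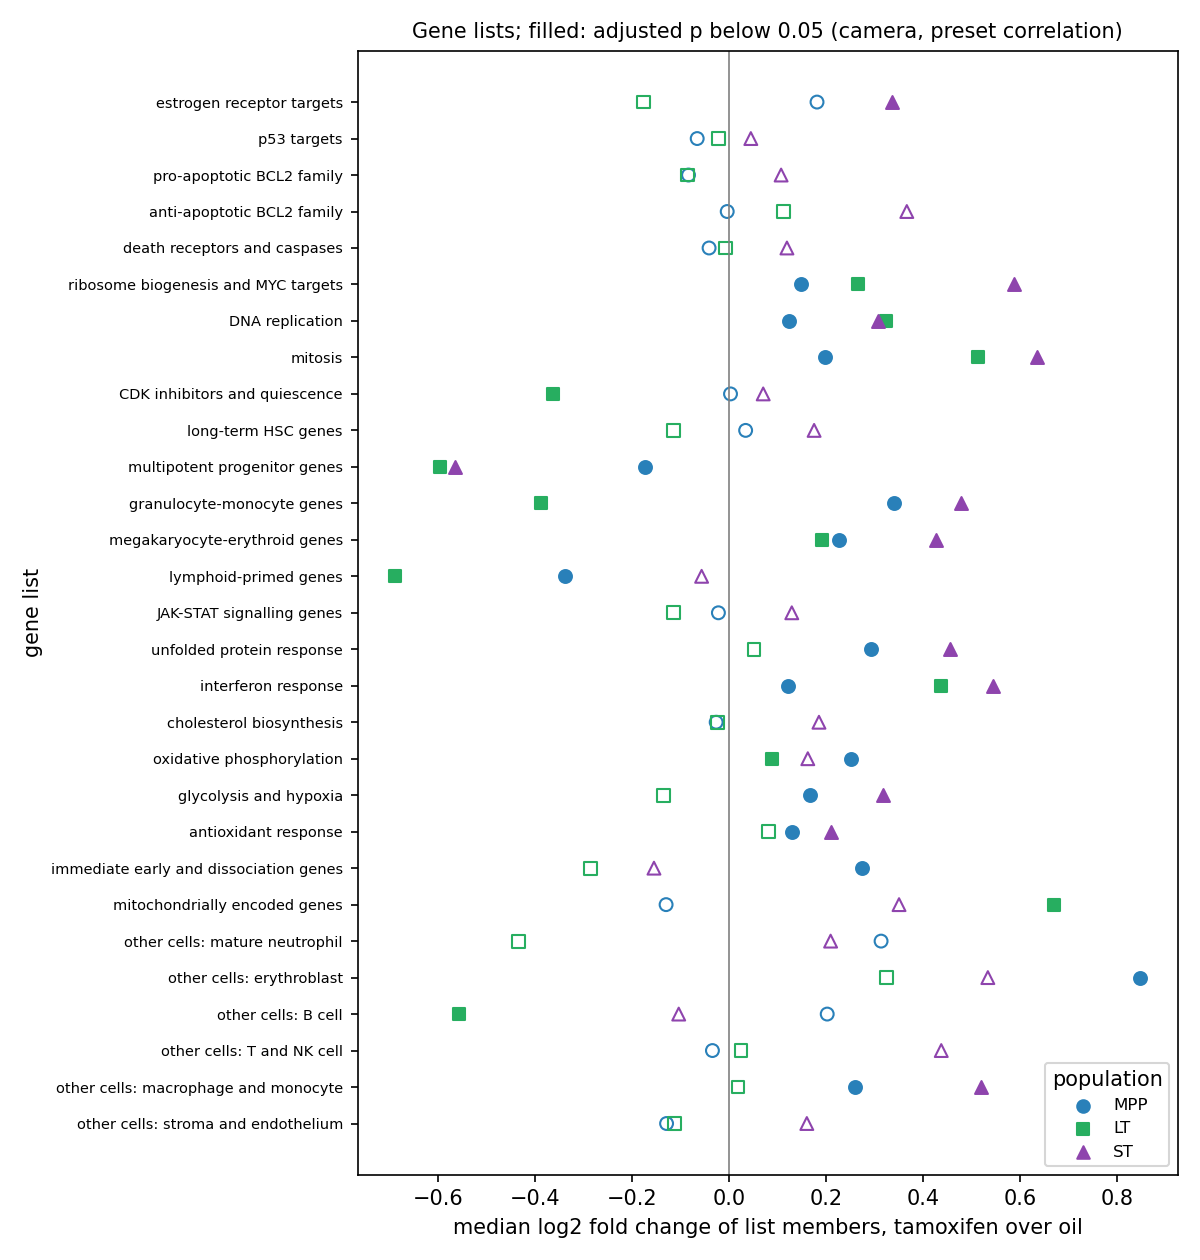
Median log2 fold change (tamoxifen against oil, horizontal axis) of the measured members of each of the 29 gene lists in MPPs, LT cells and ST cells. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, and 1 of these 39, ribosome biogenesis in ST cells, also passed with an estimated correlation. Its median was 0.59.

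The 3 populations shared part of the response. Pdgfrb passed in all 3. All 8 genes that passed in MPPs passed in ST cells with the same direction, 5 higher and 3 lower, where independent lists would share 0.301 and 0.108. LT and ST cells shared 8 higher genes (1.2 by independence) and 18 lower genes (1.44), and none in opposite directions. Among the shared falls were Pdgfrb, Satb1, Mdga1 and Dhrs3, and, chosen after their values were seen, Nlrc3, Mmp2 and the T cell receptor gene Trbc1. Ldha, Ncaph, Coro2a, Eif2s1 and Slfn9 rose in both. MPPs and LT cells shared 1 lower gene, Pdgfrb (0.00832 by independence). Across genes, which are not independent replicates, the fold changes correlated at Pearson 0.148 (Spearman 0.176) between MPPs and LT cells, 0.244 (0.225) between MPPs and ST cells, and 0.223 (0.234) between LT and ST cells. No library was shared between these comparisons, but the shared fit gave each gene the same variance in all of them. The overlaps given by independence can therefore be too low, though a shared variance sets no direction. If LT and ST libraries with the same letter came from the same mice, their common deviations would give a covariance of 0.00908, against 0.0416 observed. Effects that passed in 1 population and not in another were not thereby shown to differ, so the differences were tested directly.

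The tamoxifen effect differed between ST and LT cells in 8 genes, 6 with the higher effect in ST cells and 2 with the lower, with 1860 at an unadjusted p under 0.05. Cs, the citrate synthase, stood at 116 ± 12.9 in oil and 221 ± 8.82 with tamoxifen in ST cells, and at 217 ± 12.6 and 229 ± 18.6 in LT cells (difference of log2 fold changes 0.86, limma adjusted p = 0.0389). Eno1, a glycolytic enolase, rose in ST cells and stood at 190 ± 2.7 and 175 ± 39.5 in LT cells (1.00, 0.0389). Gstm1, a glutathione transferase, fell in LT cells and stood at 69.6 ± 21.6 and 93 ± 7.96 in ST cells (1.24, 0.0389). Atp8b4 fell in LT cells and stood at 132 ± 21.1 and 179 ± 17.7 in ST cells (2.32, 0.0212), and Mtus1 stood at 10.6 ± 0.975 and 29.1 ± 5.09 in ST cells and at 10.1 ± 3.99 and 5.75 ± 0.445 in LT cells (2.02, 0.0389). After quantile normalisation 2 differences were higher and 5 lower, edgeR called 0 (1778 unadjusted), and DESeq2 called 68 and 57. Cs (0.0614), Eno1 (0.0633) and Gstm1 (0.0505) lost the call after quantile normalisation. With the replicate number as a block 34 genes passed, with the letter as a block across LT and ST cells 125, with library weights 99, with length and GC trends removed 25, with a stricter filter 24, with only the groups compared 2 and without trend and robust settings 0. No gene passed without LT oil library A or C, LT tamoxifen library C, ST oil library B or ST tamoxifen library C (1545 to 1979 at an unadjusted p under 0.05), 1 passed without LT oil library B, ST oil library A or ST tamoxifen library B, and 122, 53, 80 and 19 without LT tamoxifen library A or B, ST oil library C or ST tamoxifen library A.

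Between MPPs and ST cells 1 gene differed, Tcof1, which encodes the nucleolar protein treacle. It stood at 49.1 ± 8.92 in oil and 93.1 ± 4.33 with tamoxifen in ST cells and at 114 ± 17.1 and 95.7 ± 2.84 in MPPs (difference -1.17, limma adjusted p = 0.0441, 0.000126 to 0.237 over the alternatives). At an unadjusted p under 0.05 there were 1742 genes, edgeR called 0 (1708 unadjusted) and DESeq2 128. Between MPPs and LT cells limma called 0 genes (808 at an unadjusted p under 0.05), edgeR 0 (877 unadjusted) and DESeq2 11. Duration and population differ together in both comparisons. The Tcof1 call was lost without MPP oil library 1 or 2, MPP tamoxifen library 1 or 2, ST oil library A or B, or ST tamoxifen library C, with nothing added (0.0504), with the replicate number as a block (0.107) or without trend and robust settings (0.214). Library weights gave 155 genes against ST cells, the shared fit without LT tamoxifen library A 164 and only the groups compared 36, and the replicate block gave 9 against LT cells. Omissions gave up to 35 genes (without ST oil library C) against ST cells and 5 (without LT tamoxifen library B) against LT cells.

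As a measure of how the populations differed without the drug, ST and LT cells were compared in oil. If the separately numbered ST libraries were handled apart, that difference cannot be told apart from population here. Some genes were higher in ST cells, with Mpo at 93 ± 9.33 in LT and 1100 ± 133 in ST cells, the neutrophil elastase gene Elane at 4.09 ± 2.63 and 173 ± 44, Ctsg at 2.77 ± 1.6 and 147 ± 44.2, Cd48 at 11.2 ± 3.58 and 99.6 ± 15.3, and Plac8 at 20 ± 5.02 and 151 ± 26. Of the long-term HSC list, members lower in ST cells were Mllt3 (281 ± 23.6 in LT and 99 ± 5.84 in ST cells), Prdm16 (84 ± 1.51 and 22.9 ± 1.91) and Eng (174 ± 2.77 and 67.2 ± 12.7). Also lower in ST cells were Ermap at 272 ± 45.9 and 17.4 ± 2.04, Cpox at 135 ± 7.53 and 25.8 ± 6.57, and Aqp1 at 122 ± 19 and 17.4 ± 7.34. Of the mitosis and DNA replication lists, Cdk1 (22.5 ± 4.98 and 65.9 ± 12.6), Ndc80 (18.9 ± 2.37 and 63 ± 5.91), Pcna (208 ± 24.8 and 454 ± 65.5) and Prim1 (41.9 ± 4.21 and 102 ± 10.3) were higher in ST cells, while of the CDK inhibitor and quiescence list Foxo3 (357 ± 14.6 and 187 ± 37.7) and Foxo1 were lower.

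In this comparison 4104 genes passed, 1802 higher and 2302 lower in ST cells, with 5564 at an unadjusted p under 0.05. The groups did not overlap in 6366 genes (44.2%, against 10% by chance). Of the ribosome biogenesis list and the unfolded protein response list, lower members in ST cells were Cad at 140 ± 8.4 in LT and 49.9 ± 7.81 in ST cells, Ddx21 at 183 ± 23.6 and 110 ± 8.4, and Asns at 47.9 ± 4.65 and 9.4 ± 1.13. Of the oxidative phosphorylation list, Ndufa4 (43.6 ± 1.82 and 178 ± 27.8), Cox7b and Cox5b were higher in ST cells. Pdgfrb was higher in ST cells (19.7 ± 1.61 and 37 ± 4.84, limma adjusted p = 0.0159, 0.000318 to 0.066 over the alternatives), a call lost without LT oil library A (0.0541), LT oil library B (0.0501) or ST oil library A (0.066). Ermap, Ces2g, Myh10, Atp1b2, Spire1 and Tgm2 were lower in ST than in LT cells in oil and rose with tamoxifen in ST cells. The same holds for Cad, Ddx21 and Asns and, chosen after their values were seen, for Cs and Tcof1. Both comparisons use the ST oil libraries, as do the differences of response given for Cs and Tcof1. The lists were not tested as sets here. Leaving out 1 library at a time gave 3158 to 3942 genes, each time fewer than the 4104 of the full data.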

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

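The tests of length and GC content, of genes without reads, of mixing between populations and of genes highest in LT cells were chosen only after the result was seen.

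A test of the difference between the ST and LT effects of tamoxifen singled out 8 genes, given as the difference of log2 fold changes with limma's adjusted p. These were Cs (0.86, 0.0389), Mtus1 (2.02, 0.0389), Gstm1 (1.24, 0.0389), Atp8b4 (2.32, 0.0212), Eno1 (1.00, 0.0389), BC035044 (1.56, 0.0452), Gm14391 (-1.04, 0.0452) and ENSMUSG00000091171 (-1.27, 0.0389). The test between MPPs and ST cells singled out Tcof1 (-1.17, 0.0441). Outliers were not tested in groups of 3 libraries, and no column of values was left unused.

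With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 8 genes in MPPs, 60 in LT cells, 1386 in ST cells and 4104 between ST and LT cells in oil, where the highest other split called 1, 1, 2 and 1, and in each comparison 1 of the 10 splits reached the real count. For the ST and LT and the MPP and ST differences chance was not excluded: of 100 splits 7 called at least the 8 genes of the ST and LT difference (highest other 1474) and 14 at least the 1 gene of the MPP and ST difference (highest other 434). For the MPP and LT difference the real split called 0 genes, which all 100 splits reach by definition, so the count says nothing about chance there (highest other 86, with 808 genes at an unadjusted p under 0.05 in the real split by limma, 0 calls by edgeR and 11 by DESeq2). The highest splits of the ST and LT and of the MPP and LT differences exchange oil and tamoxifen in 1 population. That of the MPP and ST difference exchanges them in ST cells and mixes them in MPPs. Splits of this kind call many genes because they add tamoxifen effects, a structure of the samples. Since the splits keep real tamoxifen effects, they cannot decide on chance for a difference of effects, and chance stays open there.

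In ST cells the ribosome biogenesis list was higher and Malat1 and Neat1 lower with tamoxifen. Length and GC trends as the whole cause are argued against, since 90.2% of the 1293 testable calls held after their removal (93.6% with another smoother). Unequal depth is argued against by 1333 calls at 1 common depth, of which 1237 were among the calls made without thinning. The common depth was an effective library size of 3017842, and reads in listed genes still differed between the thinned libraries. A trend with expression level is argued against for ribosome biogenesis, since its median lay at percentile 100 of 10000 random lists matched on expression, though for the antioxidant list it stays open (percentile 88.89). A different share of nuclear or unspliced RNA may also lower antisense and other noncoding transcripts and stays open as untested, beside a response of the cells to tamoxifen.

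LT tamoxifen library A stood apart from the other LT libraries. A less complex library fits with 419 genes at 0 reads at 1 common depth, against 219 to 335 in the other LT libraries, although ST tamoxifen library C had 434. The common depth was 1 effective library size, so reads in listed genes were not equal. The deviation of LT tamoxifen library A was also compared with gene features. This deviation followed GC content (Spearman across genes -0.37) and length (0.19) more than that of any other library. The next largest values, 0.32 and 0.17, belong to the other LT tamoxifen libraries, whose deviations are taken partly against library A, and outside this group they reached 0.15 and 0.13. The correlation of library A with LT oil was higher by 0.0439 than with MPP or ST oil (0.0404 and 0.0431 in the other LT tamoxifen libraries), which argues against a swap of the whole library but leaves a minor share of other cells open, so a technical difference may underlie part of its distance, and no biological explanation was tested.

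Several genes lower in ST than in LT cells in oil rose in ST cells with tamoxifen, and both comparisons share the ST oil libraries. In a test without shared libraries, the ST effect did not follow the difference between LT and MPP cells in oil by rank. Spearman's correlation across genes was -0.0293, and -0.0567 to 0.00339 without each library. It lay under the bound of 0.05 set for shared libraries as the cause, though Pearson's 0.054 had the opposite sign and was just above that bound. The correlation covers all genes and another contrast than ST against LT cells, so it cannot decide for the genes named. Of 50 genes highest in LT cells relative to MPPs in oil, 41 were higher in ST cells with tamoxifen, 24 of them in every tamoxifen library against every oil library, and 1 of the 50, Igkc (53.7 to 209, chosen after its values were seen), is also a gene of B cells. The 50 were chosen on LT and MPP oil libraries alone and include Ermap, Ces2g, Myh10, Atp1b2, Spire1 and Tgm2. Shared ST oil libraries did not enter this choice, so the rise of 41 of the 50 does not come from choosing genes on them. All 50 were still read against the same ST oil libraries, and genes are not independent replicates. A common deviation of these libraries therefore stays open. If LT cells were mixed in, the 50 genes would imply a median share of 16.3% LT cells (quartiles 4.22% and 29.8%). The bounds of this test of mixing were set once its values were known, so it carries no weight in favour. Genes higher in MPPs had a median log2 change of -0.0437 (interval -0.34 to 0.0946 from resampled genes, not libraries). Such a share of LT cells would give -0.257 only if LT cells expressed none of these genes. They did express them, as with Flt3 (83.1 in LT and 142 in ST oil) and Satb1 (59.5 and 91.1), so a smaller fall would follow. A change in the mix of sorted cells and a change within ST cells therefore cannot be told apart.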

How the results depend on the processing

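The removal of length and GC trends, the thinning to 1 depth, the fit without LT tamoxifen library A, the log2 scale with nothing added, edgeR and DESeq2 were chosen after seeing the data. Counts that moved by over 1.5 times are given below, and the cause was not tested. Counts follow the order MPPs, LT cells, ST cells, then the ST and LT, MPP and LT, and MPP and ST differences, and each sentence names those that moved.

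At an adjusted p below 0.10 there were 15 genes in MPPs, 221 in LT and 2189 in ST cells, 87 for the ST and LT difference and 11 for MPP and ST. Adding 0.1 in place of 1 gave 3 genes for MPP and LT. Adding nothing gave 2 for MPP and LT and 0 for MPP and ST (1708 at an unadjusted p under 0.05). A stricter filter gave 24 for ST and LT and 3 for MPP and ST. Quantile normalisation gave 98 in LT cells and 9 for MPP and ST. Fitting only the groups compared gave 19 in MPPs, 3 in LT cells, 2 for ST and LT, 2 for MPP and LT and 36 for MPP and ST. Without trend and robust settings there were 2 in MPPs, 22 in LT cells, 0 for ST and LT (1830 unadjusted) and 0 for MPP and ST (1621). Library weights gave 67 in MPPs, 235 in LT cells, 99 for ST and LT, 2 for MPP and LT and 155 for MPP and ST. Removing length and GC trends gave 5 in MPPs, 25 for ST and LT and 10 for MPP and ST, and with a least-squares smoother 5, 14 and 12. Thinning gave 1 for MPP and LT. With LT tamoxifen library A left out of the shared fit there were 22 in MPPs, 2121 in ST cells and 164 for MPP and ST. EdgeR gave 5 in MPPs, 0 for ST and LT (1778 unadjusted) and 0 for MPP and ST (1708). DESeq2 gave 28 in MPPs, 300 in LT cells, 125 for ST and LT, 11 for MPP and LT and 128 for MPP and ST.

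With the replicate number as a replicate block across oil and tamoxifen there were 34 genes for ST and LT, 9 for MPP and LT and 0 for MPP and ST (1768 unadjusted), and Esr1 in ST cells had an adjusted p of 0.0554 (0.0029 to 0.0743 over the alternatives). With the letter as a replicate block across LT and ST cells there were 125 for ST and LT. Oil and tamoxifen libraries of the same number correlated at -0.033 to 0.13 in their deviations, over 0.1 in 2 of 9 pairs. LT and ST libraries of the same letter correlated at 0.052 to 0.14, over 0.1 in 1 of 6. Each of these 6 correlated best with its own letter, a hint from the data only. The labels do not say that numbers or letters pair the libraries, so the main fit assumed no pairing. Weak correlations do not exclude it.

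Of the 87 list tests, 39 passed, 1 with an estimated correlation and 18 with fry. Where a list passed in the main fit or in the alternative, the direction reversed in 1 case. This was oxidative phosphorylation in LT cells without LT tamoxifen library C (camera adjusted p = 0.987, and 2.26e-09 without LT tamoxifen library A). With a stricter filter the correlations of the tamoxifen effects were 0.252 between MPPs and LT cells, 0.328 between MPPs and ST cells and 0.347 between LT and ST cells.

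Leaving out each library in turn gave 0 to 40 genes in MPPs, 9 to 330 in LT cells, 654 to 1378 in ST cells, 0 to 122 for ST and LT, 0 to 5 for MPP and LT, 0 to 35 for MPP and ST, and 3158 to 3942 between ST and LT cells in oil. It gave 36 to 40 lists and correlations of 0.094 to 0.2 (MPPs and LT cells), 0.186 to 0.262 (MPPs and ST cells) and 0.17 to 0.259 (LT and ST cells). Over all alternatives, named genes kept their direction and side of the threshold in 4573 cases, fell short of it in 385 and newly passed in 70. In 3 cases the direction changed and the gene passed in neither fit, and in 0 it changed where the gene passed in either fit. For lists these counts were, in the same order, 1016, 104, 24, 70 and 1. The planned fit without a filter is void, since the filter removed no gene. Depth limits the rarest transcripts most, as for Greb1, which rested on 4 reads or fewer over each oil group.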

Other observations

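The genes named here were chosen after their values were seen, and no explanation was tested for them.

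Some genes outside the lists changed in both LT and ST cells. Themis, a gene of T cell development, fell by 1.53 on the log2 scale in LT cells and by 1.35 in ST cells, and Trbc1, a constant region of the T cell receptor, by 2.10 and 1.60, while the list of T and NK cell markers did not pass (camera adjusted p = 0.939 and 0.838). Nlrc3 fell by 1.63 and 1.99, and Mmp2, a matrix metalloproteinase, by 1.71 and 1.71. The coagulation factor gene F5 rose by 1.35 and 1.46 on the same scale and Clca1 by 1.36 and 1.27. Each passed limma at an adjusted p under 0.05 in both populations.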
